A study of Homo sapiens with 8 samples.

How the data were processed

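Libraries of total RNA, 4 of EnzaR and 4 of LNCaP cells, were compared, and groups were taken from the sample labels. The deposited table held 57905 Ensembl genes with raw read counts per gene and FPKM for the 8 libraries. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2 and the build hg19 (GRCh37), without roles. The annotation release and the strand setting of counting are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart. The authors' FPKM equalled the count divided by exonic length and column total for 463240 values within 0.0051, and FPKM was not used further. The deposited counts were used as they were, and 0 rows named no gene. Gene names were matched by Ensembl identifier for 39538 genes, which held 98.96% of counts. Coordinates are those of the deposited table. Transcript GC content came from a GRCh38 annotation by identifier and was available for 97.3% of the genes tested.

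Total counts were 18054075, 18248939, 16682669 and 18103509 in the EnzaR libraries (siNC 1 and 2, siYAP1 1 and 2) and 17657484, 17964615, 17543894 and 17547773 in the LNCaP libraries (control, EV-siNC, EV-siYAP1, EV-siCII). A count of 3 corresponded to 0.164 to 0.18 CPM. Counts of the 2 siNC libraries differed with a chi-square per degree of freedom of 6.89 and those of the 2 siYAP1 libraries of 8.11. The lowest value of any pair of libraries was 5.03, between EV-siNC and EV-siCII, so none was a copy of another. The pairs of EV libraries, at 5.03, 5.29 and 5.67, thus differed by less than the EnzaR replicates did.

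The EnzaR groups were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, robust quasi-likelihood fit, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled over the libraries compared. The common dispersion was 0.0075. Gene lists were tested with camera in limma 3.58.1 on voom values with an inter-gene correlation of 0.01, with an estimated correlation and fry beside it. With an estimated correlation, camera rests on the residual degrees of freedom of the 4 libraries. It then has little power to call a list, whatever the correlation. There were 32 lists with 731 entries, of which 721 matched a gene, and a list needed 3 measured members. Lists, alternatives, designs and the rule for named genes were set before the data were examined. The rule took YAP1, NR2F2, WWTR1 and 1 further gene, then the 12 largest log2 fold changes per direction among genes with an adjusted p under 0.05, a mean of 5 CPM in either group and groups that did not overlap, and up to 4 members of each called list. Identifiers without a name were left out, 3 of the 12 that rose, and so were genes on the Y chromosome. Some genes that the rule took, and a list, are not reported here.

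LNCaP groups have 1 library each. Log2 ratios of TMM-scaled CPM were computed with a prior count of 2 over genes with 10 CPM in either library, with the 10 largest ratios per direction and up to 4 members of each list outside the 1st to 99th percentile named. Identifiers without a name at 2-fold numbered 2, 1 and 1 in the 3 comparisons. Percentiles come from 10000 random lists drawn within 20 expression bins. Intervals are exact binomial limits at 95% and cover counting error only. Shared libraries were handled with 100 simulated sets drawn with the EnzaR dispersion.

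The EnzaR test was tested on simulated data for 14948 genes: 98% of 2-fold and 79% of 1.5-fold changes were recovered, 5.35% of calls were false, and 0 calls arose with no change. For EV-siNC against control, simulated over 9065 genes, 100% of 4-fold changes passed 2-fold, with 2 other genes. In both simulations the changed genes were drawn among well-counted genes only, and the counts held no GC or length trend between libraries. These rates therefore do not cover genes with low counts or libraries with such a trend. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, filters and thresholds, a block on replicate number, all 8 libraries in the fit, and each replicate left out. Leaving out a replicate leaves a lone library that is assumed to vary like the other group. A correction for GC content and length was added after seeing the data, as a smooth surface per library (mgcv 1.9.3).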

Results

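RNA sequencing was carried out on 8 libraries of human prostate cancer cells. EnzaR cells are resistant to enzalutamide, an antiandrogen drug, and were kept in medium with 10 uM of the drug. They received 40 nM of a control siRNA (siNC) or of siRNA against YAP1 for 48 h, with 2 libraries per group. LNCaP is an androgen-sensitive prostate cancer line. Its cells were labelled as a vehicle control without vesicles (control), or were given extracellular vesicles (EVs) from EnzaR cells that had been depleted of YAP1 (EV-siYAP1), of COUP-TFII (EV-siCII) or treated with control siRNA (EV-siNC), for 48 h, with 1 library per group. The labels name neither the vehicle nor whether the control was cultured alongside the cells given vesicles. COUP-TFII is the nuclear receptor encoded by NR2F2, and YAP1 is the transcriptional co-activator at the end of the Hippo pathway. Total counts lay between 16682669 and 18248939 per library. Mitochondrially encoded transcripts took 6.65% to 6.83% of counts in the EnzaR libraries and 4.76% to 5.37% in the LNCaP libraries. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

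The comparison within EnzaR cells asked which transcripts differ when YAP1 is depleted. YAP1 (ENSG00000137693, chromosome 11, 101981192 to 102104154, hg19) was at 57.4 and 47.64 CPM in the siNC libraries and at 5.79 and 7.07 CPM in the siYAP1 libraries. Its mean fell from 52.5 ± 6.9 to 6.43 ± 0.91 CPM (SD, n = 2), a log2 fold change of -3.02 with SE 0.154 (edgeR quasi-likelihood test, adjusted p = 2.07e-10). NR2F2 was at 44.9 ± 0.83 CPM in siNC and 43.8 ± 3.32 CPM in siYAP1 libraries (SD, n = 2), with adjusted p = 0.874 in the edgeR test. WWTR1, the paralog of YAP1 known as TAZ, had 3 to 6 counts per EnzaR library and was not tested.

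Among 14948 genes tested, 872 were higher and 930 lower in siYAP1 than in siNC libraries at an adjusted p under 0.05 (edgeR), and 19 and 78 of these differed by at least 2-fold. The largest rise among named genes was that of CCND3, a D-type cyclin of the G1 phase (chromosome 6, 41902671 to 42018095), from 61.8 ± 2.71 to 164 ± 4.24 CPM (SD, n = 2, log2 fold change 1.41, SE 0.099, edgeR adjusted p = 4.25e-08). PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis, rose by 1.25 on the log2 scale (SE 0.113). BANF1, a chromatin-binding protein of the nuclear envelope, rose by 1.03 (SE 0.106). DIO3, which inactivates thyroid hormone, rose by 1.02 (SE 0.125), and PYGO2, a co-activator of Wnt signalling, by 0.91 (SE 0.101). The transcription factor gene KLF2 and RENBP, GLYCTK and ZMYND10 rose by 1.02, 0.95, 0.94 and 0.90. Among the genes with the largest falls, the keratin gene KRT80 (chromosome 12, 52562780 to 52585784) went from 6.15 ± 0.12 to 1.66 ± 0.19 CPM (SD, n = 2, log2 fold change -1.88, SE 0.264, edgeR adjusted p = 0.000432). ADD3, an adducin of the membrane skeleton, had a log2 fold change of -1.56 (SE 0.163). The matrix glycoprotein gene TNC, the Golgi mannosidase gene MAN2A1, the acyl-CoA synthetase gene ACSL5 and LGR4, a receptor for R-spondins, had log2 fold changes of -1.47, -1.48, -1.45 and -1.39. ZDHHC20, SNX10, IQGAP2 and the long noncoding RNA DRAIC had values of -1.35, -1.35, -1.32 and -1.26. SERF1B (-1.33) is uncertain, since SERF1A is a near-identical copy.

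**Figure D1:**
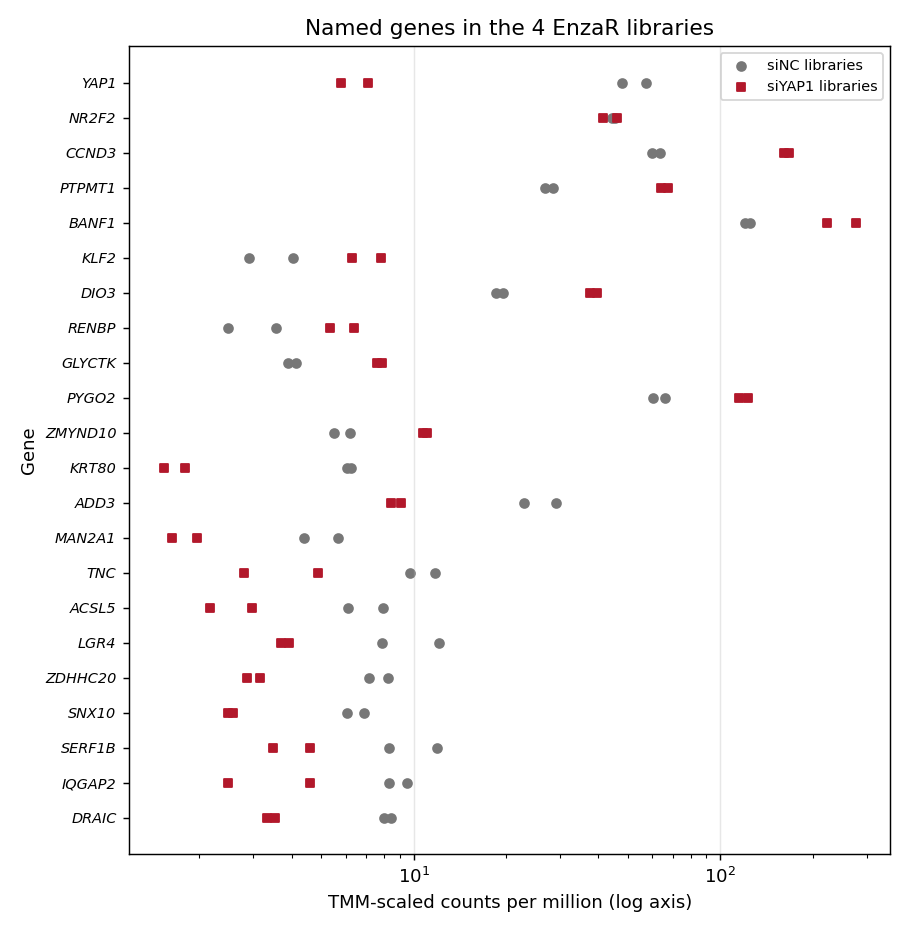
Each point is 1 EnzaR library, with TMM-scaled CPM on a log axis and the named genes on the vertical axis; circles are siNC and squares siYAP1 libraries. YAP1 lay at 47.64 and 57.4 CPM in siNC and at 5.79 and 7.07 CPM in siYAP1 libraries, while the points of NR2F2 overlapped.

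Of 30 gene lists tested with camera, 5 were called. Integrated stress response genes shifted higher (camera adjusted p = 8.88e-06, and adjusted p = 0.649 with an estimated correlation), with 10 of 27 tested members higher and 1 lower over all genes tested, and the same numbers when adjusted over the list alone. The adjusted value of 0.649 is shared by most lists and does not rank them. For this list the estimated correlation was -0.00244, below the 0.01 assumed. The unadjusted camera p still rose from 5.92e-07 to 0.0304, so the rise does not reflect correlation between members. It reflects the few degrees of freedom that 4 libraries leave when the correlation is estimated. The fry test gave an adjusted p = 0.0792. CHAC1, which degrades glutathione, rose from 21.5 ± 4.05 to 37.6 ± 2.27 CPM (SD, n = 2), and ASNS, asparagine synthetase, from 147 ± 1.99 to 204 ± 6.53 CPM (SD, n = 2). TRIB3 and SLC3A2 rose by 0.43 and 0.40 on the log2 scale. The member that fell was XPOT, a tRNA export factor (-0.35). Without EnzaR_siYAP1 replicate 1 the list was called, with a median log2 fold change of 0.232 against 0.223 with all libraries (camera adjusted p = 1.74e-06, range over the alternatives 1.74e-06 to 0.649), while 0 members passed the threshold. The number of members higher was 3 without EnzaR_siNC replicate 1, 4 without EnzaR_siNC replicate 2 and 4 after a GC and length correction. Cytosolic ribosomal protein genes shifted higher (camera adjusted p = 9.98e-07, and adjusted p = 0.649 with an estimated correlation), with 7 of 30 members higher and 14 when adjusted over the list alone. Their estimated correlation was 0.874, far above the 0.01 assumed, so the smaller p-value overstates the evidence. With that estimate the unadjusted camera p was 0.346, and fry gave an adjusted p = 0.336. RPL18, RPL27A, RPS2 and RPS9 rose by 0.44, 0.37, 0.38 and 0.37. These genes have many near-identical pseudogenes and are uncertain, and the median of the list also differed between replicates, by 0.146 in siNC and by -0.182 in siYAP1 (replicate 2 against replicate 1). The list median was 0.242 with all libraries, 0.14 without EnzaR_siYAP1 replicate 1 and 0.156 without EnzaR_siNC replicate 1, and the list was called in both cases (camera adjusted p = 0.00101 and 0.0133, range over the alternatives 1.66e-11 to 0.649).

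Stemness-associated genes shifted lower (camera adjusted p = 0.0179, and adjusted p = 0.649 with an estimated correlation), with 6 of 12 tested members lower, also when adjusted over the list alone. ALDH1A3, an aldehyde dehydrogenase, fell from 8.24 ± 0.42 to 3.62 ± 0.28 CPM (SD, n = 2). The integrin genes ITGA2 and ITGA6 had log2 fold changes of -0.86 and -0.62, and the Polycomb gene BMI1 of -0.63. The number of members lower was 0 without EnzaR_siYAP1 replicate 1, 2 without EnzaR_siNC replicate 1, 4 without EnzaR_siNC replicate 2, 3 without EnzaR_siYAP1 replicate 2 and 2 after the GC and length correction. Markers of another type of prostate cancer line had a median log2 fold change of -0.42 and were not called (camera adjusted p = 0.0795), with 2 of 5 lower, also when adjusted over the list alone, KRT7 (-1.69) and EPHA2 (-0.52). That list was called lower after the GC and length correction (camera adjusted p = 0.00232, range over the alternatives 0.0011 to 0.649). Hippo pathway components shifted lower (camera adjusted p = 0.0496, and adjusted p = 0.649 with an estimated correlation) with 4 of 21 members lower, also when adjusted over the list alone. These were the kinases TAOK3 (-0.68) and TAOK1 (-0.48), the atypical cadherin FAT1 (-0.41) and AMOTL2 (-0.51). Fatty acid synthesis and uptake genes shifted lower (camera adjusted p = 0.0496, and adjusted p = 0.649 with an estimated correlation), with 5 of 21 members lower, and 5 lower and 1 higher when adjusted over the list alone. They included ACSL5, ACSL1 (-0.57), the desaturase FADS1 (-0.42) and the elongase ELOVL7 (-0.57). The median of the fatty acid list went from -0.199 to -0.079 after the GC and length correction, with 3 members lower and 1 higher (camera adjusted p = 0.0236, range over the alternatives 0.0148 to 0.649). With DESeq2 size factors neither the Hippo nor the fatty acid list was called (camera adjusted p = 0.0534 and 0.0678). YAP/TAZ target genes were not called (camera adjusted p = 0.092), with 1 of 12 members lower, AMOTL2, and 0 when adjusted over the list alone.

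Without EnzaR_siYAP1 replicate 1, 15 genes were higher and 11 lower (edgeR), although 2434 of 15683 genes had an unadjusted p under 0.05, beside 784 expected by chance. The genes called higher and lower with all libraries then had median log2 fold changes of 0.317 and -0.507, against 0.416 and -0.564, and all 1802 kept their direction in these fits, which share 3 libraries. The stemness, Hippo and fatty acid synthesis lists had medians of -0.356, -0.237 and -0.159 without that library, against -0.515, -0.301 and -0.199, and were not called (camera adjusted p = 0.0526, 0.172 and 0.215), while the stress response and ribosomal lists were. Without EnzaR_siNC replicate 1, where 234 genes were higher and 829 lower, those 3 lists had medians of -0.482, -0.222 and -0.19 and were not called (camera adjusted p = 0.0626, 0.186 and 0.17). Over the alternatives the adjusted p ranged from 0.000137 to 0.649 for the stemness list and from 0.0138 to 0.649 for the Hippo list. The ribosomal, Hippo and fatty acid synthesis lists had 0 called members without EnzaR_siYAP1 replicate 1, and 0, 1 and 2 without EnzaR_siNC replicate 1. They had 2, 2 and 4 without EnzaR_siNC replicate 2, and 15, 2 and 3 without EnzaR_siYAP1 replicate 2. Without EnzaR_siNC replicate 2, 579 were higher and 538 lower, and without EnzaR_siYAP1 replicate 2, 940 and 516. The YAP/TAZ targets were called lower without EnzaR_siNC replicate 2 (camera adjusted p = 0.0248), without EnzaR_siYAP1 replicate 2 (0.0283) and after the GC and length correction (0.0172, 2 members lower), but had an adjusted p = 0.649 with an estimated correlation and all libraries. Mitotic and G2/M genes were not called with all libraries (camera adjusted p = 0.174, and adjusted p = 0.649 with an estimated correlation, 3 of 30 members higher and 3 lower), but were called lower without EnzaR_siNC replicate 1 (camera adjusted p = 0.0121, 9 members lower, range over the alternatives 0.0121 to 0.85). Further lists not called with all libraries were called without EnzaR_siYAP1 replicate 2 (antigen presentation, mitochondrially encoded and nuclear oxidative phosphorylation genes higher, markers of another type of prostate cancer line lower) or after the GC and length correction (steroid conjugation and chaperone genes higher, nuclear receptors and basal epithelial genes lower). Each of these lists had a camera adjusted p = 0.649 with an estimated correlation and all libraries. Scaling by library totals alone gave 291 higher and 1416 lower, so 17% of calls were higher, against 48.4% with TMM. After a correction for GC content and length, chosen after seeing the data, 391 were higher and 222 lower (63.8% higher), and Hippo components had a median of -0.045 and were not called (camera adjusted p = 0.135).

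The first LNCaP comparison, EV-siNC against control, asked what vesicles from resistant cells do to sensitive cells. It has 1 library per group and no replicate check, so no test was made, and intervals are 95% exact limits for counting error only. Transcripts of metallothioneins, small metal-binding proteins, were lower in the EV-siNC library. MT2A was at 17.2 CPM against 79.2 in control (log2 ratio -2.20, interval -2.39 to -2.02), MT1G at 4.29 against 20.06, MT1X at 5.06 against 18.43 and MT1F at 5.39 against 16.32. SLC39A10, a zinc importer, was at 32.4 CPM in EV-siNC and 8.25 in control (log2 ratio 1.96, interval 1.71 to 2.25). DENND4A, ZNF407 and the kinase gene TBK1 had log2 ratios of 1.05, 1.04 and 1.03. SMN1 had 2.30 but is uncertain, since SMN2 is a near-identical copy, and the metallothionein genes resemble one another too. Among 9056 genes above the floor of 10 CPM, 5 were 2-fold higher and 6 lower, 2 of the latter without a name. Between replicates, these numbers were 2 and 1 in EnzaR siNC and 7 and 2 in EnzaR siYAP1.

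Lists were placed among 10000 random lists matched on expression, and 7 of 28 lay outside the 1st to 99th percentile. Between the replicates of each EnzaR group 1 list did, the ribosomal proteins. The median log2 ratio of p53 targets was 0.158 (percentile 99.99), with 20 of 22 members above 0, among them CCNG1 (0.70), the p53 inhibitor gene MDM2 (0.59), RRM2B (0.57) and SPATA18 (0.56). Mitotic genes had a median of -0.31 (percentile 0.09), with 6 of 8 members below 0, among them CDC20 at -0.68, BIRC5 at -0.64, PLK1 at -0.56 and FOXM1 at -0.35. Of the 30 genes on that list, 8 passed the floor here and 5 in EV-siYAP1 against EV-siNC. Some of the 8 therefore passed through the control library alone, and lie below 0 by selection. Cholesterol synthesis genes had a median of -0.209 (percentile 0.01), with 18 of 23 members below 0, among them DHCR7 at -0.38 and INSIG1 at -0.33, and 5 above 0, among them CYP51A1 at 0.42. Nuclear oxidative phosphorylation genes had a median of -0.179 (percentile 0.01), with 25 of 30 members below 0. NF-kB genes (-0.247), integrated stress response genes (0.009) and mitochondrially encoded mRNAs (-0.033) had percentiles of 0.24, 99.46 and 99.63. The log2 ratio in this comparison had a Spearman rho of -0.537 with GC content across genes, which are not independent replicates. After a correction for GC content and length, the NF-kB genes lay at percentile 10.85 and the mitochondrially encoded mRNAs at 92.64.

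The second comparison, EV-siYAP1 against EV-siNC, asked whether the effect of the vesicles depends on YAP1 in the donor cells. Hypoxia and glycolysis genes had a median log2 ratio of -0.295 (percentile 0), with 25 of 26 members below 0. LDHA, lactate dehydrogenase A, was at 270.0 CPM in EV-siYAP1 and 437 in EV-siNC, VEGFA at 158 and 228, ENO1 at 1535 and 2191, and PFKFB4 at 68.8 and 110. NDUFA4L2, a hypoxia-induced mitochondrial subunit, was at 157 and 280 CPM (log2 ratio -0.84, interval -0.90 to -0.77). p53 targets had a median of 0.151 (percentile 100), with 18 of 22 above 0, among them the cell cycle inhibitor gene CDKN1A at 1107 against 732 CPM, and RRM2B at 47.0 against 30.9. DNA replication genes had a median of -0.172 (percentile 0.21), with FEN1 at -0.55, MCM4 at -0.54 and MCM2 at -0.44. Endoplasmic reticulum chaperones had 0.118 (percentile 99.92). Steroid conjugation genes had -0.15 (percentile 0.77), with UGT2B15 at -0.43 and UGT2B17 at -0.37, which are near-identical and uncertain. Against the control library, EV-siYAP1 had medians of -0.413 for the hypoxia genes (percentile 0), 0.31 for p53 targets (percentile 100) and -0.393 for DNA replication genes (percentile 0). Chaperones (percentile 96.82) and steroid conjugation genes (percentile 6.05) lay inside the 1st to 99th percentile. The log2 ratio against control had a Spearman rho of -0.466 with GC content across genes. After the GC and length correction the hypoxia, p53 and DNA replication medians were -0.311, 0.404 and -0.235 (percentiles 0, 100 and 0.07). Of 9136 genes, 1 was 2-fold higher and 4 lower, beside 2 and 1 between the EnzaR siNC replicates and 7 and 2 between the siYAP1 replicates. The SD of log2 ratios was 0.183 here and 0.166 in EV-siCII against EV-siNC. Both were below the 0.194 and 0.206 between the EnzaR siNC and siYAP1 replicates, so these EV libraries differed by less than replicates of the other line. The gene 2-fold higher was SERF1B (1.18, uncertain), and those lower were SCNN1G, a subunit of the epithelial sodium channel (-1.24), DIO3 (-1.10), SMN1 (-1.33, uncertain) and 1 without a name. YAP1 was at 58.4 to 66.3 CPM in the 4 LNCaP libraries when all 8 libraries were scaled together, and NR2F2 at 48.3 to 53.4.

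The third comparison, EV-siCII against EV-siNC, asked the same of COUP-TFII. Hypoxia and glycolysis genes had a median log2 ratio of -0.358 (percentile 0), with 23 of 26 below 0. NDUFA4L2 was at 115 CPM in EV-siCII against 280 in EV-siNC (log2 ratio -1.28, interval -1.35 to -1.20), BHLHE40, a hypoxia-responsive repressor, at 10.7 against 24.8, PFKFB4 at 61.2 against 110 and VEGFA at 136 against 228. P4HA1 and BNIP3 had log2 ratios of -0.73 and -0.67. p53 targets lay on the other side of 0 from the EV-siYAP1 comparison, with a median of -0.14 (percentile 0), GDF15 at 827 against 1299 CPM and MDM2 at 46.0 against 59.7. Mitotic genes had a median of 0.292 (percentile 99.9), with FOXM1 at 0.52 and PLK1 at 0.41. Here 7 mitotic genes passed the floor, against 5 in EV-siYAP1 against EV-siNC. Some of the 7 therefore passed through the EV-siCII library alone, and lie above 0 by selection. Endoplasmic reticulum chaperones had 0.138 (percentile 100), with CALR at 0.24 and HSPA5 at 0.23. Integrated stress response genes had -0.142 (percentile 0), with STC2 at -0.49 and ATF3 at -0.37. Fatty acid oxidation genes (0.102), DNA replication genes (0.136) and vesicle biogenesis genes (0.1) lay above percentile 99, although DNA replication genes lay at 98.4 after the GC and length correction, and ribosomal proteins (-0.079) and immediate early genes (-0.094) below percentile 1. In EV-siYAP1 against EV-siNC, fatty acid oxidation genes (0.087) lay at percentile 98.99, or 99.74 after the correction. Vesicle biogenesis genes (0.061) lay at 96.36 there. Against the control library, EV-siCII lay inside the 1st to 99th percentile for p53 targets (-0.024, percentile 74.21), mitotic genes (-0.036, percentile 15.99), stress response genes (-0.053, percentile 51.73), DNA replication genes (-0.029, percentile 22.62) and vesicle biogenesis genes (-0.007, percentile 93.22). The hypoxia genes (-0.379), chaperones (0.045), fatty acid oxidation genes (0.065), ribosomal proteins (-0.178) and immediate early genes (-0.205) lay outside it there too, the last at percentile 1.44 after the GC and length correction. MT2A was at 36.5 CPM in EV-siCII and 17.2 in EV-siNC. Of 9072 genes, 1 was 2-fold higher, MT2A, and 6 lower, among them SCNN1G (-1.80), NDUFA4L2, BHLHE40 and DIO3 (-1.11), beside 2 and 1 between the EnzaR siNC replicates and 7 and 2 between the siYAP1 replicates.

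**Figure D2:**
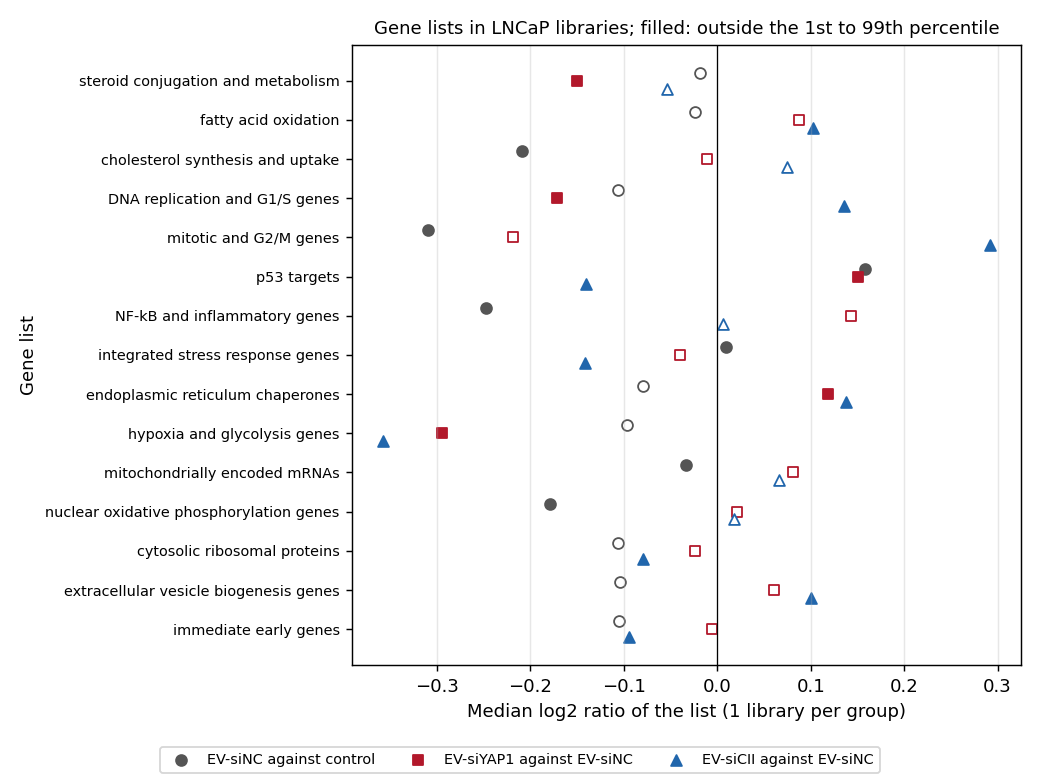
Each point is the median log2 ratio of a gene list between 2 LNCaP libraries; circles are EV-siNC against control, squares EV-siYAP1 against EV-siNC and triangles EV-siCII against EV-siNC, and filled points lie outside the 1st to 99th percentile of 10000 random lists. Hypoxia and glycolysis genes lay at -0.295 and -0.358 in EV-siYAP1 and EV-siCII against EV-siNC, and p53 targets at 0.151 and -0.14.

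The return towards control was examined next. Of the 5 genes 2-fold higher in EV-siNC than in control, 4 were at least 1.5-fold lower in EV-siCII than in EV-siNC (SMN1, SLC39A10, DENND4A and TBK1), and 1, SMN1, was in EV-siYAP1. Of the 6 genes 2-fold lower, 3 were at least 1.5-fold higher in EV-siCII (MT1G, MT2A and MT1F) and 0 in EV-siYAP1. The EV-siNC library is on both sides of this comparison. In 100 simulated sets with no effect, the totals reached at most 2 for either vesicle type, against 7 for EV-siCII and 1 for EV-siYAP1, but those sets held at most 2 genes 2-fold higher and 2 lower that could return. The sets also drew genes independently, while 3 of the 7 are metallothioneins. SMN1 is uncertain, and DENND4A and TBK1 lay near the floor in EV-siNC (10.39 and 11.21 CPM). The metallothionein and SLC39A10 differences rest on the single control library. The covariance of the EV-siNC/control ratio with EV-siCII/EV-siNC was -0.02, beside a simulated -0.0194, and with EV-siYAP1/EV-siNC it was -0.000359, beside -0.0193. The simulated sets, drawn with the EnzaR dispersion, were noisier, with an SD of log2 ratios of up to 0.201. The observed SD was 0.166 in EV-siCII and 0.183 in EV-siYAP1 against EV-siNC. The simulated covariances therefore cannot decide whether a return took place. The pair that shares no library, EV-siNC/control with EV-siYAP1/EV-siCII, had a Pearson r of 0.42 across genes, which are not independent replicates, with simulated values between -0.0293 and 0.0272. Its covariance was 0.0197, beside a simulated 4.28e-05, and over 8739 genes with a GC value r was 0.412 before and 0.361 after the GC and length correction. That covariance is by definition the difference of the 2 covariances above, so it is not an additional result. It cannot tell a return in EV-siCII from a move of EV-siYAP1 further from control. Against control, 2 and 10 genes were 2-fold higher and lower in EV-siCII, and 23 and 18 in EV-siYAP1. These numbers were not corrected for GC content and length. The log2 ratios had a Spearman rho with GC content of -0.472 in EV-siCII and -0.466 in EV-siYAP1 against control.

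Finally, genes called in EnzaR cells after YAP1 siRNA were followed in the EV-siYAP1 against EV-siNC ratio of LNCaP cells, which shares no library with them. The 804 genes higher in EnzaR had a median log2 ratio of -0.015 (percentile 0.12), and the 734 genes lower in EnzaR had 0.045 (percentile 100). After a correction of the LNCaP ratios for GC content and length the medians were -0.019 (percentile 0) and 0.019 (percentile 97.99), and with both cell lines corrected -0.025 (percentile 0.17) and 0.017 (percentile 88.04). The genes called higher and lower in EnzaR also had medians of -0.134 (percentile 0) and 0.332 (percentile 100) in EV-siNC against control, and of 0.01 (percentile 3.42) and -0.038 (percentile 0) in EV-siCII against EV-siNC. After the correction these were -0.02 (percentile 48.31) and 0.073 (percentile 100), and -0.013 (percentile 0) and 0.002 (percentile 66.22). The EV-siNC library enters each of these ratios.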

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

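The correction for GC content and length was chosen after seeing the data, and all other alternatives were planned. YAP1 stayed lower under each alternative run, with log2 fold changes from -3.17 to -2.76. Against 872 higher and 930 lower genes in EnzaR siYAP1, the correction gave 391 and 222, the library totals 291 and 1416 (median log2 fold change of all genes -0.129, against -0.025), an adjusted p under 0.01 gave 154 and 202, and a 2-fold minimum 19 and 78. DESeq2 gave 928 and 475, with 66.1% higher, over the 9117 genes to which it gave an adjusted p, against 14948 in edgeR. Leaving out 1 replicate gave 15 to 940 higher and 11 to 829 lower, both lowest without EnzaR_siYAP1 replicate 1, where 24 of the genes called were also called with all libraries and 1528 of the 1802 called with all libraries had an unadjusted p under 0.05. Without EnzaR_siNC replicate 1 there were 234 higher and without EnzaR_siNC replicate 2 there were 579 higher and 538 lower. Without EnzaR_siYAP1 replicate 2 there were 516 lower. The cause was not tested, but EnzaR_siYAP1 replicate 1 also stood apart on length (rho of its deviation from the EnzaR mean -0.356, against -0.077, 0.184 and 0.281). Replicate numbers were shared between the groups but were not shown to pair the libraries (correlation of deviations -0.08). The replicate block gave 564 higher and 845 lower genes, and the replicate block with the GC and length correction 394 and 284.

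Of 44 genes compared in EnzaR, 14 lost their call after the GC and length correction, 35 without EnzaR_siYAP1 replicate 1, 17 without EnzaR_siNC replicate 1, and 0 with limma-voom, and no direction turned. The 44 genes included some without a call, such as NR2F2 (edgeR adjusted p = 0.874), which had no call to lose. CCND3, PTPMT1, BANF1, DIO3, PYGO2, KRT80 and ADD3 stayed called in every alternative that gave a value, and NR2F2 stayed not called. The 5 called lists became 3 with DESeq2 size factors (without the Hippo and fatty acid synthesis lists), 0 with an estimated correlation, 0 with fry, 10 after the GC and length correction, 9 with the replicate block added to it, and 2 to 10 when 1 replicate was left out, with 2 without EnzaR_siYAP1 replicate 1, 3 without EnzaR_siNC replicate 1 and 10 without EnzaR_siYAP1 replicate 2. The 3 included mitotic genes, not among the 5. After the GC and length correction YAP/TAZ targets were called lower (camera adjusted p = 0.0172, range over the alternatives 0.0172 to 0.649) and Hippo components were not (adjusted p = 0.135, range 0.0138 to 0.649).

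In LNCaP, with 5 and 6 genes 2-fold higher and lower in EV-siNC against control, a CPM floor of 5 gave 19 and 10, a floor of 20 gave 2 and 2, library totals 9 higher, the GC and length correction 3 higher, and a 1.5-fold minimum 239 and 27. For EV-siYAP1 against EV-siNC, with 1 and 4, a floor of 5 gave 5 and 9, a floor of 20 gave 0 and 2, and 1.5-fold 31 and 36. For EV-siCII against EV-siNC, with 1 and 6, a floor of 5 gave 5 higher, and 1.5-fold 7 and 36. At 1.5-fold, simulated sets with no change held up to 90, 78 and 80 genes in both directions together, and EnzaR replicates differed in 67 higher and 16 lower (siNC) and 60 and 14 (siYAP1). The median of mitochondrially encoded mRNAs in EV-siNC against control changed sign, to 0.032 with library totals and 0.008 after the GC and length correction. Returns of EV-siNC-induced genes, 5 over both vesicle types, were 2 at 2-fold and 3 with a floor of 20. EnzaR-called genes with a 2-fold minimum had medians of -0.114 and 0.149 in EV-siYAP1 against EV-siNC (percentiles 8.42 and 98.36). Corrected for GC and length, those called lower had 0.019 (percentile 97.99), and 0.017 (percentile 88.04) when the EnzaR calls were corrected too. The settings foreseen for a table without counts did not apply. With 1 LNCaP library per group, depth limits the ratios of genes near 10 CPM, and no list percentile measures variation between cultures.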

Other observations

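The tests of explanations for the GC and length trend, for the metallothioneins and for the hypoxia genes were chosen after these patterns were seen. EnzaR siNC and LNCaP control libraries, which differ in line, drug and transfection together, were compared with all 8 libraries scaled together, with 33.6% of 9773 genes differing by at least 2-fold. Cell cycle genes were higher in EnzaR, with 24 of 25 DNA replication genes and 28 of 28 mitotic genes at least 2-fold higher than in the single LNCaP control library. CDC6 was at 98.2 ± 3.85 CPM in EnzaR siNC (SD, n = 2) and 2.01 in LNCaP control, CDC45 at 70.6 ± 1.95 and 3.41, and DLGAP5 at 28.4 ± 7.12 and 0.56. The prostate-specific antigen gene KLK3 was at 1183 ± 34.9 CPM in EnzaR siNC (SD, n = 2) against 47.3 in LNCaP control, KLK2 at 207 ± 10.1 against 19.3, and TRPM8 at 50.2 ± 6.18 against 0.84.

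Other genes were higher in LNCaP. VIM was at 0.85 ± 0.2 CPM in EnzaR siNC (SD, n = 2) and 272 in LNCaP control, MDK at 0.85 ± 0.26 and 353, and TMEFF2 at 0.05 ± 0.08 and 156. ETV1 had 0 counts in both EnzaR siNC libraries and 415 in LNCaP control. Interferon-stimulated genes had a median of -1.36 (percentile 0.01) and replication-dependent histones of -1.58 (percentile 0.01). Vesicle biogenesis genes in EnzaR after YAP1 siRNA were not called as a list (camera adjusted p = 0.709), and their median (0.018) and mean (-0.077) differed in sign. Members went both ways, with SDC4 at -0.81, CD82 at -0.63 and SDCBP at -0.42, and CHMP2A at 0.41 and CD81 at 0.39, genes picked after their values were seen.

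Genes called after YAP1 siRNA followed GC content (Spearman rho 0.482 with the log2 fold change across genes) and length (-0.301), with a median GC of 60.2% in genes called higher and 42.6% in those called lower. After the correction, 424 of the 1802 genes called, 23.5%, stayed called in the same direction, so most lost their call. This argues against a trend between libraries as the cause of every call only as far as the smooth correction removed the trend. The median log2 fold changes of genes called higher and lower went from 0.416 and -0.564 to 0.272 and -0.307. The calls thus ended with smaller folds, at a median SE of 0.12 before and 0.107 after. Such trends also arose without YAP1 siRNA in the sequenced cells, with a rho of -0.537 between the LNCaP EV-siNC and control libraries, and replicates of 1 group differed, with rho 0.288 for length and -0.108 for GC in siYAP1 and -0.089 and -0.03 in siNC (replicate 2 against replicate 1). Without EnzaR_siYAP1 replicate 1, whose deviation from the EnzaR mean had a rho of -0.356 with length (-0.077 for replicate 2, 0.281 and 0.184 for siNC), 26 genes were called (1063 without EnzaR_siNC replicate 1 and 1117 without EnzaR_siNC replicate 2), but 2434 had an unadjusted p under 0.05, beside 784 expected by chance, and the medians of the genes called with all libraries were 0.317 and -0.507 (median SE 0.138). A part of the calls may reflect library composition, and a response to YAP1 depletion that favours short GC-rich transcripts stays open.

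Metallothionein mRNAs, a family singled out after their values were seen, were lower in each of the 3 EV libraries than in control, with medians over 4 genes of -2.02 in EV-siNC, -2.37 in EV-siYAP1 and -1.09 in EV-siCII, while SLC39A10 was higher (1.96, 1.93 and 1.12). GC content and length are argued against by a corrected median of -1.85 in EV-siNC, where SLC39A10 had a corrected value of 1.58. Its corrected values were 1.48 in EV-siYAP1 and 0.82 in EV-siCII, the latter below 2-fold. A corrected metallothionein median was taken for EV-siNC only. Reads moved between near-identical copies are argued against by the summed family, which was at least 2.18-fold higher in control than in any EV library. A difference of the control library alone cannot be told apart from an effect of the vesicles, since there was 1 control library, and the labels name neither its vehicle nor whether it was cultured alongside the others. A lower zinc supply in the cultures with vesicles is a candidate explanation that was not tested, and SLC30A1, a zinc exporter gene, had a log2 ratio of -0.18 (interval -0.56 to 0.19). Apart from SLC39A10, the measured zinc transporter genes of these 2 families lay between -0.32 (SLC30A3) and 0.58 (SLC39A6) in EV-siNC against control. They went both ways.

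Hypoxia and glycolysis genes were lower in EV-siYAP1 and EV-siCII than in EV-siNC. GC content and length are argued against, since the corrected medians were -0.298 and -0.349. A high value in the EV-siNC library alone is argued against, since EV-siNC against the single control library had a median of -0.097. The medians against control were -0.413 in EV-siYAP1 and -0.379 in EV-siCII, and -0.311 and -0.323 after the GC and length correction. The simulated ranges were -0.084 to 0.072 and -0.11 to 0.087. Those sets drew genes independently and held no GC or length trend. The ranges may therefore be too narrow for such a list and do not decide. A difference in culture density or oxygen, or an effect of YAP1 or COUP-TFII depletion in the donor cells, may each account for the lower values. None of these was tested.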
